A study of Mus musculus with 6 samples.

How the data were processed

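Cell-level matrices of 6 splenocyte libraries were analysed, 3 from mice on ND and 3 from mice on MCDHFD. The deposited values are raw UMI counts for 32285 genes, per the file headers and a check that all are whole numbers. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 9.1.0 and analysed in Seurat 4.3.0. Per the file headers, Cell Ranger 9.0.1 wrote ND replicates 1 and 3 and MCDHFD replicates 1 and 2, and version 7.2.0 wrote ND replicate 2 and MCDHFD replicate 3. The last 2 hold filtered lists of 3409 and 3807 barcodes, and the other 4 hold 1114720, 1117783, 1345921 and 1338822 barcodes. Reads were not realigned.

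Barcodes with at least 1000 UMIs, at least 400 genes and at most 10% mitochondrial UMIs were kept as cells. The mitochondrial limit removed 252, 2 and 372 barcodes in ND replicates 1 to 3 and 904, 772 and 16 in MCDHFD replicates 1 to 3. Scrublet, run per library, predicted 75, 0 and 59 doublets in ND and 241, 198 and 0 in MCDHFD, and these were removed. It found none in the 2 libraries with filtered lists, so no cells were removed there. Kept cells held 88.4%, 99.5% and 83.4% of the UMIs in ND replicates 1 to 3 and 77.4%, 78.7% and 98.9% in MCDHFD replicates 1 to 3.

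Cells were integrated with Harmony on 30 principal components of 2000 variable genes and clustered with 20 neighbours (Leiden, resolution 1.2). Clusters were named from marker lists. A cluster was left unnamed with fewer than 3 markers of its class detected or raised at least 2 times, or with as many raised markers of another class. The same held with more markers of another class than of its own among its top 10 genes, with a pancreatic acinar gene there, or with over 60% of its cells from 1 library. It also held for T cell clusters whose CD8 or CD4 markers were raised less than 2 times on average, and for clusters with low UMIs and no marker of their class in the top 10. CD8 T cells were clustered again on 1000 variable genes and 20 components, without the 394 genes that differed by diet. UMIs were summed per library and class, and classes with at least 20 cells in every library were tested, which left out plasma cells (19 cells in ND replicate 2).

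Genes were tested in edgeR (quasi-likelihood) with Benjamini-Hochberg adjustment, with a model of diet alone fixed before the data were examined. The form of the barcode list as a second term was fixed at the same time as a second way to test. The choice to name genes from it was made after the data were seen, because the libraries with filtered lists stood apart in both diets. The rule names Trnp1 in each class, and in CD8 T cells the 12 genes with the largest fold change in each direction, or 5 in other classes. They must have adjusted p under 0.05, mean log2 CPM of at least 4 and no overlap between the diets. Immunoglobulin genes, T cell receptor segments other than the delta constant gene, haemoglobin and unnamed gene models are left out. Up to 4 members of each described list with the smallest p are added, and with fewer than 5 genes the 5 smallest p are given as values. For cells with against without Trnp1 UMIs the rule takes 10 genes each way and asks for 1 direction in every library instead of no overlap.

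The 37 gene lists were fixed without the data and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists with at least 5 measured members. Trnp1-positive shares were compared after thinning each cell to 1000 UMIs. Cells with and without Trnp1 UMIs were paired within log2 0.2 of UMIs within each library, and sums needed at least 10 cells. Alternatives covered DESeq2, upper-quartile normalization, no filter on low counts, other cell limits, doublets kept, each library left out and other cluster resolutions. Added after the data were seen were the 4 libraries with unfiltered lists alone, a batch term of 3 levels (ND replicate 1, the other 3 libraries with unfiltered lists, and the 2 with filtered lists), a doublet score limit of 0.25 and the planned settings on the model with list form. For shares, gene lists and the interaction, list form as a term was also added then.

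The tests were checked on simulated data. With a log2 change of 1, the CD8 comparison recovered 93% of changed genes, the monocyte and macrophage comparison 76%, the CD8 against CD4 interaction 51% and the comparison by Trnp1 100%. A list shifted by log2 0.5 ranked 1 of 35. For the CD8 and the monocyte and macrophage comparisons, the spread came from the fit with list form. No difference between library types was simulated there, and the test used diet alone. The other simulations used a fixed dispersion, lower than the common dispersion of any class (0.0603 to 0.131). These rates therefore do not give the power in the real data. Analyses ran in Python 3.11.15 with scanpy 1.11.5, and in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.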

Results

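The libraries hold splenocytes of mice kept for 7 weeks on ND or on MCDHFD, with 3 libraries per diet, from a study of splenic CD8 T cells with high Trnp1 and liver fibrosis. The titles of the latter 3 samples name the diet MCD and the growth protocol names it MCDHFD, which is used here. Droplet-based 3' sequencing gave a count of unique molecules (UMIs) for each gene and cell barcode. Total UMIs were 56714190, 21956506 and 45223393 in ND replicates 1 to 3, and 61446640, 62238012 and 21259837 in MCDHFD replicates 1 to 3. After the quality filters, 6533, 3273 and 4952 cells remained in the ND libraries and 6606, 6566 and 3527 in the MCDHFD libraries. Their median UMIs per cell were 5601, 5066 and 5891.5 for ND, and 5942.5, 6201.5 and 4469 for MCDHFD. Predicted doublets (75, 0 and 59 in ND, 241, 198 and 0 in MCDHFD) were then removed, and shares are given of the cells left.

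ND replicate 2 and MCDHFD replicate 3 stood apart from the other 4 libraries. Their barcode lists were already filtered, to 3409 and 3807 barcodes, and their headers name another Cell Ranger version. Of their 3273 and 3527 kept barcodes at most 95 and 101 occur in any of the unfiltered lists. The unfiltered lists were not 1 set either: of 6533 kept barcodes in ND replicate 1, 2168 to 2426 occur in those of the other 3 libraries, while 4941 of 4952 in ND replicate 3 occur in that of MCDHFD replicate 2. List form as a term stands for all that set these 2 libraries apart. Mitochondrial transcripts took a median of 0.571% and 1.68% of UMIs in them, against 3.73% to 3.96% in the 4 libraries with unfiltered lists. Each comparison of the diets was therefore read from a model with diet alone and from a model with diet and list form, with the log2 difference inside each form beside it. Unless another source is named, log2 values and verbs such as rose or fell refer to the model with diet and list form (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, positive values higher with MCDHFD). All p-values measure the spread between libraries, since the labels do not say whether each library is 1 animal. MCDHFD replicates 1 and 2 were more alike in their gene counts than any other pair within a diet. Their chi-square per degree of freedom was 16.7, against 74.8 for ND replicates 1 and 3 and 300 to 448 for pairs across list forms. The tests treated them as separate replicates, and p-values are too small if they are not.

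CD8 T cells and cells of the monocyte and macrophage class took larger shares of the MCDHFD spleens. CD8 T cells made up 14.4% ± 0.811 (SD, n = 3) of the cells with MCDHFD and 9.30% ± 0.47 with ND, a log2 change of 0.63. Monocytes and macrophages made up 9.16% ± 1.52 and 4.50% ± 1.28, a log2 change of 1.03. Both passed with diet alone (edgeR, Benjamini-Hochberg adjusted p = 0.0482 for each). B cells, the most abundant class, took 43.0% ± 9.35 with MCDHFD and 59.0% ± 6.47 with ND, and CD4 T cells 15.03% ± 3.65 and 10.9% ± 1.93. These shares did not pass with diet alone (edgeR, Benjamini-Hochberg adjusted p = 0.136 for B cells and 0.268 for CD4 T cells). They passed with list form in the model (0.0017 and 0.013), which for shares was added after the data were seen. The shares of CD8 T cells, B cells and monocytes or macrophages did not overlap between the diets, which gives the smallest value a two-sided exact permutation test of 3 against 3 allows (p = 0.1). Leaving out any 1 library ended the CD8 call with diet alone, at adjusted p between 0.0718 and 0.229 (edgeR, Benjamini-Hochberg), and the monocyte and macrophage call held only without ND replicate 2 (0.0336).

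**Figure D1:**
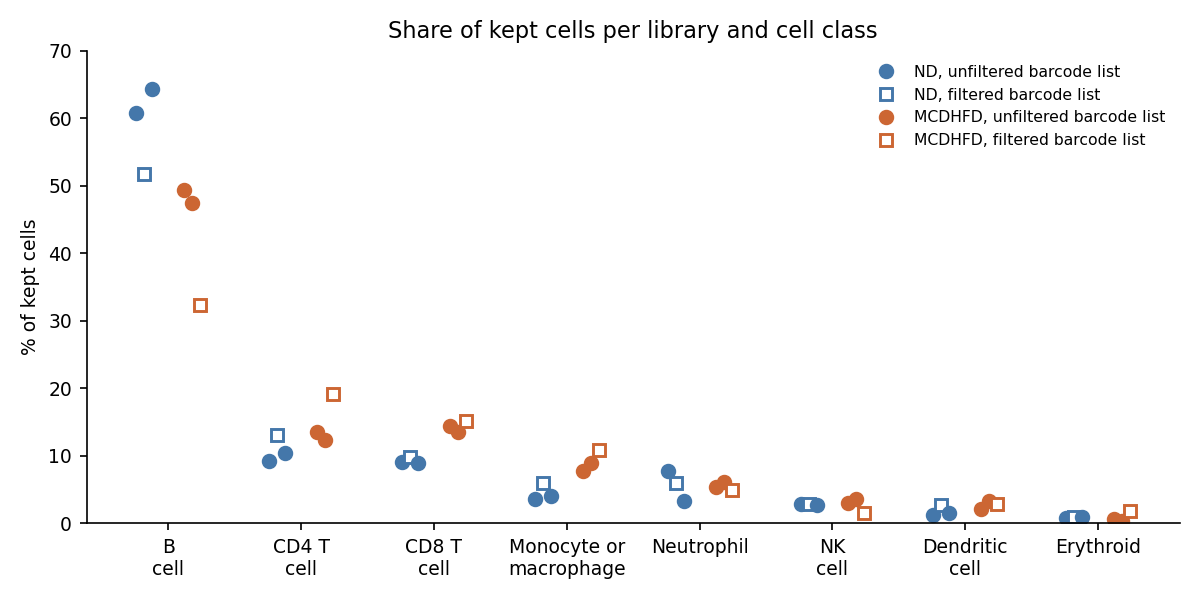
Percent of cells in each of 8 cell classes, 1 point per library, blue for ND and orange for MCDHFD, with open squares for the libraries with filtered barcode lists. CD8 T cells averaged 14.4% with MCDHFD and 9.30% with ND.

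With all 6 libraries, no change was called in the shares of the remaining tested classes. The dendritic cell share was called among the 4 libraries with unfiltered lists alone. Neutrophils made up 5.44% ± 0.614 with MCDHFD and 5.71% ± 2.26 with ND, NK cells 2.73% ± 1.07 and 2.77% ± 0.0438, dendritic cells 2.76% ± 0.58 and 1.80% ± 0.8, and erythroid cells 0.929% ± 0.774 and 0.853% ± 0.0471. None of these passed with diet alone (edgeR, Benjamini-Hochberg adjusted p = 0.988, 0.988, 0.353 and 0.988). Clusters left unnamed held 5.48% ± 4.18 of MCDHFD cells and 3.83% ± 1.46 of ND cells. Within CD8 T cells, clustered without the 394 genes that differed by diet, naive cells took 16.5% ± 5.07 with MCDHFD and 16.9% ± 4.65 with ND, and central memory cells 16.8% ± 1.71 and 19.03% ± 2.58. Effector cells took 1.55% ± 0.934 and 1.81% ± 0.592, and interferon-stimulated cells 2.36% ± 0.704 and 2.69% ± 1.01. No CD8 state passed with diet alone (edgeR, Benjamini-Hochberg adjusted p = 0.887 for each), and 62.8% ± 5.73 and 59.6% ± 6.23 of the CD8 T cells had no named state. The 394 genes left out include 16 state markers, so this test cannot show that the states were unchanged. Clustering of all cells gave CD8 cluster 13, with Ccl5 as its leading gene. It held 186, 84 and 113 of 587, 322 and 439 CD8 T cells in ND replicates 1 to 3. In MCDHFD replicates 1 to 3 it held 195, 190 and 93 of 916, 861 and 534. Each of these MCDHFD shares was smaller than any in ND.

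Trnp1, which encodes a nuclear protein studied as a regulator of cortical growth, was the gene the study is named for, and it was higher in CD8 T cells of every MCDHFD library than of any ND library. Its gene (ENSMUSG00000056596) lies on the minus strand of chromosome 4, from 133491100 to 133498550 in mm10, and overlaps no other annotated gene. In CD8 T cells it reached 48.9, 77.2 and 190 CPM (counts scaled to the sum of the library and class) in MCDHFD replicates 1 to 3, against 5.27, 8.89 and 3.69 in ND replicates 1 to 3. The log2 change was 4.15 (SE 0.357) with diet alone and 3.96 (SE 0.213) with list form in the model, 3.59 among the unfiltered and 4.42 between the filtered libraries. The first did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.400) and the second did (adjusted p = 4.75e-10), as did DESeq2 with diet alone (4.14, Benjamini-Hochberg adjusted p = 2.81e-10).

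At least 1 Trnp1 UMI was found in 32.8%, 46.1% and 68.9% of CD8 T cells in MCDHFD replicates 1 to 3 and in 4.43%, 5.59% and 3.19% in ND replicates 1 to 3. With every cell thinned to 1000 UMIs the shares were 10.3% ± 7.28 and 0.614% ± 0.357 (SD, n = 3, two-sided exact permutation p = 0.1, the smallest possible). The thinned share in MCDHFD replicate 3, 18.4%, had a 95% Wilson interval from 15.3% to 21.9%, and that in ND replicate 3, 0.228%, one from 0.0402% to 1.28%. These intervals cover counting error only. B cells, which served as the background, had a Trnp1 UMI in at most 0.165% of cells of any library, at median depths of 3539 to 5625 UMIs against 6601 to 9081 in CD8 T cells. CD4 T cells carried the gene as well, with 18.9, 31.2 and 173 CPM in MCDHFD replicates 1 to 3 and 4 UMIs in all ND libraries together. Trnp1 UMIs were also seen in 3.14%, 2.59% and 23.6% of NK cells and 7.89%, 16.7% and 34.4% of erythroid cells in MCDHFD replicates 1 to 3, and in none of these cells in the ND libraries. These shares are not thinned, and erythroid median depth ran from 13459 to 62419 UMIs. Thinned, they were 2.74% ± 3.92 in NK cells (two-sided exact permutation p = 0.1) and 3.125% ± 5.41 in erythroid cells (exact permutation p = 1) with MCDHFD, against 0 with ND. In MCDHFD replicate 3 they were seen in 12.1% of neutrophils, 5% of monocytes or macrophages and 4.95% of dendritic cells, and in any other library in at most 1.47% of each. Among basophils or mast cells 4 of 7 cells in MCDHFD replicate 3 had a Trnp1 UMI, and none elsewhere.

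**Figure D2:**
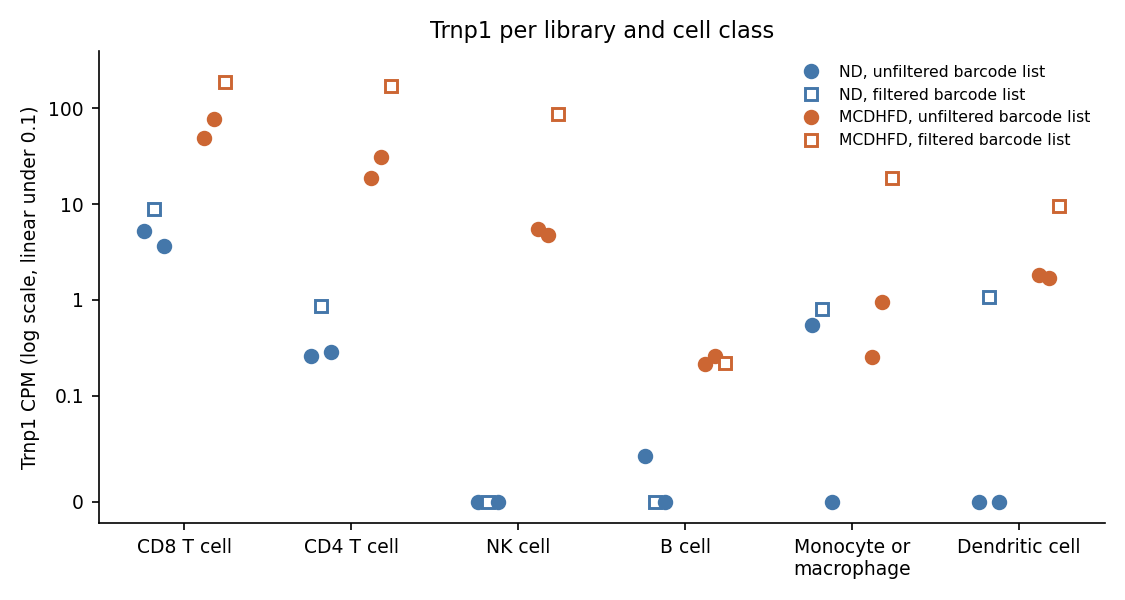
Trnp1 CPM per library in 6 cell classes on a log axis that is linear under 0.1, blue for ND and orange for MCDHFD, with open squares for libraries with filtered lists. In CD8 T cells the MCDHFD libraries reached 48.9 to 190 CPM and the ND libraries 3.69 to 8.89.

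Among the genes called in CD8 T cells, Syt6, of the synaptotagmin family of vesicle proteins, rose most, by 4.38 (SE 0.244), ahead of Trnp1. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.73 (SE 0.188), Socs3, an inhibitor of cytokine signalling, by 1.399, and Bcl3, a nuclear member of the IκB family, by 1.36. Sytl3 rose by 1.16 and Rab27a, a GTPase of secretory vesicles, by 0.99, as did the actin-binding coronin Coro2a (1.36), Cpt1a of mitochondrial fatty acid import (1.06), Slc49a4 (0.96), Eya2 (0.94) and Mid1 (0.91, with 0.17 between the filtered libraries). Hdac9, a class IIa histone deacetylase, fell by 2.06, the transcription factor Ikzf2 by 1.79 and the surface receptor Slamf7 by 1.57. Also lower were the chemokine Xcl1 (-1.34), Plac8 (-1.12), Ms4a4c (-1.05), the transcriptional inhibitor Id3 (-1.03) and Trdc (-1.45), the constant region gene of the delta T cell receptor chain. Klra7 (-1.36) and Ctla2a (-1.13) fell too, and both belong to families of near-identical genes whose reads the counting could split.

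In all, 394 of 10478 genes changed in CD8 T cells, 132 higher and 262 lower, against 1 gene with diet alone (edgeR, Benjamini-Hochberg). That gene was Syt6 (log2 4.41, adjusted p = 0.00908, 4.12 among the unfiltered and 4.47 between the filtered libraries). The next smallest p-values with diet alone belonged to Ptprm (-2.83), Slamf7 (-1.57), Trnp1 (4.15) and Ifi27l2a (-1.57), none of them past the threshold (edgeR, Benjamini-Hochberg adjusted p from 0.185 to 0.400). Unadjusted p fell under 0.05 for 345 genes with diet alone, and DESeq2 called 22. The rule for naming genes, which also asks that the diets do not overlap (10% of genes by chance), was met by 50 higher and 101 lower genes. Without 1 library the count with list form ranged from 173 to 1026. Without ND replicate 2 or MCDHFD replicate 3 (1010 and 1026), list form takes up the 1 filtered library left. Here and in every class, those fits thus rest on the 4 libraries with unfiltered lists. The Syt6 call with diet alone was lost without ND replicate 1, 2 or 3 or MCDHFD replicate 2, as it was with the replicate number as a block (edgeR, Benjamini-Hochberg adjusted p = 0.257).

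**Figure D3:**
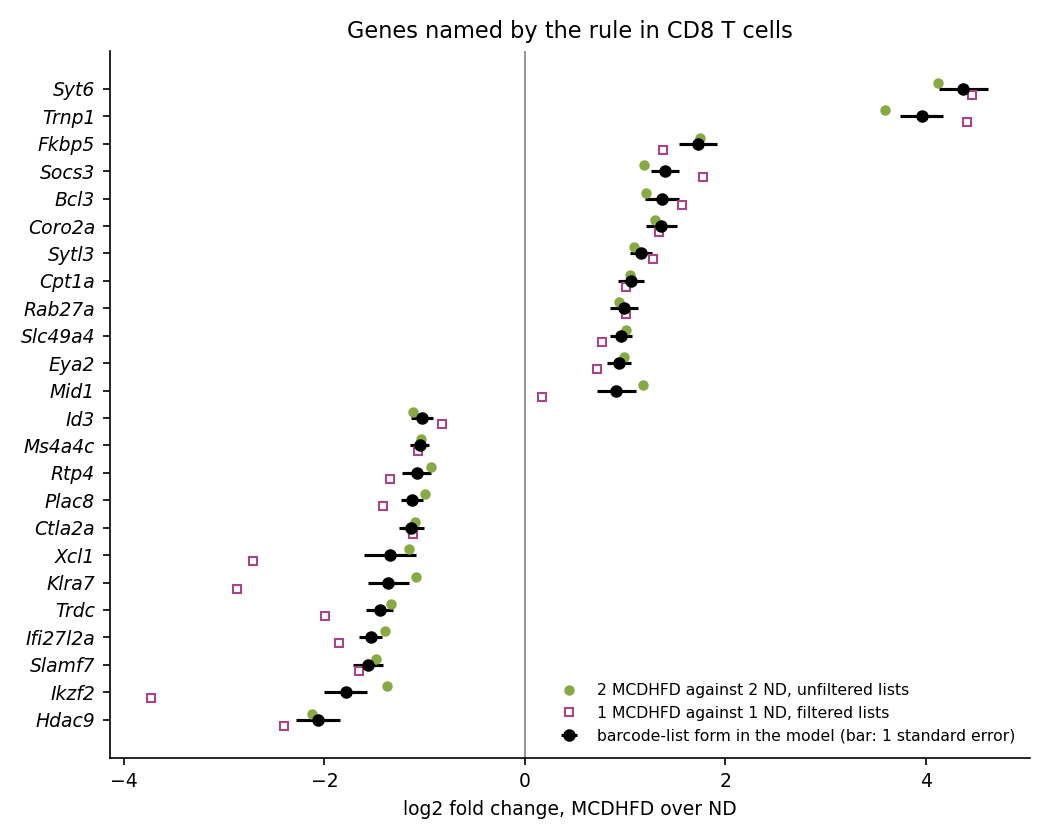
Log2 fold changes, MCDHFD over ND, of the 24 genes named by the rule in CD8 T cells, with black points and bars for the model with list form and its standard error, green points for the unfiltered and open squares for the filtered libraries. Syt6 and Trnp1 lead at 4.38 and 3.96, and Hdac9 lies lowest at -2.06.

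Genes of the type I interferon response were the group with the most members lower in CD8 T cells. Of 33 measured members 16 fell, none rose and 17 did not pass, with a median of -0.60, and 26 were lower when adjusted over the list alone. Without ND replicate 3, 3 members were lower (median -0.34). Ifi27l2a fell by 1.54, Rtp4 by 1.08, Bst2, a membrane protein that tethers viruses, by 0.77 and the DNA sensor Ifi206 by 0.62. From the list for interferon gamma and antigen presentation 5 of 25 members fell, among them the immunoproteasome subunit Psmb9 (-0.48) and the MHC class I genes H2-Q7 (-0.53) and H2-T23 (-0.43). Adjusted p was 0.235 and 0.1799 for these lists with an estimated correlation (camera, Benjamini-Hochberg).

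Of 21 memory genes 11 fell and 1 rose in CD8 T cells, among them the calcium-binding S100a4 (-0.96), S100a6 (-0.65) and S100a10 (-0.63), and 12 were lower when adjusted over the list alone. From the cytotoxicity and effector list 7 of 18 fell, including the granzymes Gzma (-2.12) and Gzmb (-2.33), the chemokine Ccl5 (-0.84) and the effector transcription factor Zeb2 (-1.40). CD8 cluster 13, with Ccl5, Ly6c2, Il2rb and Nkg7 among its leading genes, held 186, 84 and 113 of the 587, 322 and 439 CD8 T cells of the ND libraries and 195, 190 and 93 of the 916, 861 and 534 of the MCDHFD libraries. The inhibitory receptor Pdcd1 (-2.31) and Ikzf2 were among 3 of 14 exhaustion genes that fell, and Egr1 (-0.69), Egr3 (-1.07), Rel (-0.41) and Tnfrsf9 (-0.995) among 4 of 16 early activation genes. Adjusted p with an estimated correlation was 0.1799 for memory, cytotoxicity and exhaustion, and 0.208 for early activation. The naive and stem-like list moved both ways, with the survival factor Bcl2 higher (0.51) and Id3 lower.

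Oxidative phosphorylation genes lay slightly lower in CD8 T cells, with 4 of 32 past the test and 15 when adjusted over the list alone (median -0.23, adjusted p = 0.464 with an estimated correlation). Examples were Uqcrb (-0.45) and Cox6c (-0.42), subunits of the respiratory chain. Ddit4, a stress-induced inhibitor of mTORC1, rose by 1.10, and the proliferation-linked Stmn1 fell by 1.27. Markers of other cells moved as well. Igha (-2.95), Iglc2 (-0.76) and Cd79b (-0.55) of B and plasma cells and the neutrophil granule genes Ngp (-3.73) and Camp (-2.66) fell, while the macrophage genes Apoe (1.24), Vcam1 (1.73) and Lyz2 (0.63) rose. Of 35 lists tested, camera with a preset correlation called 19 (17 with diet alone), and with an estimated correlation it called none (lowest adjusted p = 0.1799, and 0.0632 with diet alone). Neither did fry (lowest adjusted p = 0.0558 and 0.0547).

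In CD4 T cells Trnp1 rose from 4 UMIs in the ND libraries to 895 in the MCDHFD libraries, a ratio of 147 in CPM with a 95% counting interval from 57.3 to 541. Of the 895 UMIs, 616 came from MCDHFD replicate 3, and the log2 difference was 5.02 among the unfiltered and 7.03 between the filtered libraries. Ston1 rose by 2.75, Fkbp5 by 1.59, the pore-forming Prf1 by 1.37 and the p53 target Bbc3 by 1.31. Ifi27l2a fell by 1.61, S100a4 by 1.44, the chemokine receptors Cxcr3 and Cxcr6 by 1.41 and 1.38, and the ubiquitin-like interferon product Isg15 by 1.34. Of 21 memory genes 11 fell and 1 rose (median -0.70), with S100a6 (-1.12) and the galectin Lgals1 (-0.86) among them, and 14 were lower when adjusted over the list alone. The type I interferon list had 11 of 32 members lower and 19 when adjusted over the list alone (Bst2 -0.80, Rtp4 -1.23), and that for interferon gamma 10 of 25 (Iigp1 -1.29). Adjusted p with an estimated correlation was 0.148 for each of these 3 lists.

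Of 19 early activation genes 6 fell and 1 rose in CD4 T cells, and the receptors Tnfrsf4 (-1.29), Icos (-0.60) and Il2ra (-0.71) were among the lower ones. Naive-state genes rose in part, with Bcl2 (1.02), Igfbp4 (0.76) and the interleukin 7 receptor Il7r (0.59) among 4 of 16, against 2 lower. Tnfrsf4, Icos and Il2ra are leading genes of CD4 cluster 16, beside Foxp3 and Ctla4. It held 324, 177 and 242 of the 596, 426 and 511 CD4 T cells of the ND libraries and 329, 318 and 193 of the 860, 788 and 677 of the MCDHFD libraries. Igfbp4 and Il7r lead cluster 12, which held the rest. Folate-cycle Mthfd1l (0.66), Mthfd1 (0.56) and the methionine salvage enzyme Mtap (0.50) rose, 3 of 22 one-carbon and methionine genes, with none lower. Adjusted p with an estimated correlation was 0.406, 0.446 and 0.446 for these lists. B cell markers were lower here too (Iglc2 -1.60, Cd79a -1.03). In all, 458 genes of 10369 changed, 176 higher and 282 lower, and 72 and 124 met the naming rule. With diet alone edgeR called 0 genes, 425 had an unadjusted p under 0.05 and DESeq2 called 39. The smallest p-values with diet alone were those of Myo6 (2.15), Cxcr3 (-1.42), Gimap7 (-1.18), Ifi27l2a (-1.61) and Ston1 (2.84), at edgeR Benjamini-Hochberg adjusted p from 0.239 to 0.450. Leaving out 1 library gave 184 to 731 genes with list form in the model.

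Whether the diet acted differently in the CD8 and CD4 classes was tested as an interaction within libraries, in a model without list form, from which the values here come. The mix of clusters inside both classes differed between the diets, as given above. The interaction was not tested within clusters, so a changed mix cannot be told apart from a change within cells. Hdac9 differed most clearly, with a diet effect of -2.06 in CD8 and 0.21 in CD4 T cells (difference -2.30, edgeR, Benjamini-Hochberg adjusted p = 5.51e-09). Ikzf2 fell further in CD8 T cells (difference -1.14). Bcl2 rose less in CD8 than in CD4 T cells (-0.50), and the sodium pump subunit Atp1b1 had effects of 0.19 in CD8 and 1.11 in CD4 T cells (difference -0.93). Lgals1 had effects of -0.03 and -0.86 (difference 0.82), Nkg7 of -0.36 and -1.15 (0.83), and vimentin (Vim) of 0.36 and -0.32 (0.64). Of 11190 genes 73 differed, 41 with the higher effect in CD8 and 32 in CD4 T cells, and 99 with list form by class in the model, where the Hdac9 difference was -2.23. For Trnp1 itself the log2 difference was -2.94 (SE 0.855), larger in CD4 T cells, and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.153). It rests on 4 Trnp1 UMIs in CD4 T cells of all ND libraries together. Mean CPM was 105 with MCDHFD and 5.95 with ND in CD8 T cells, and 74.3 and 0.466 in CD4 T cells. The Trnp1 difference passed with list form by class in the model (-2.92, adjusted p = 0.00087), and without any 1 of the MCDHFD libraries (adjusted p = 0.0274 to 0.0286). It did not pass without ND replicate 1, 2 or 3 (adjusted p = 0.422, 0.344 and 0.221), nor in the 4 libraries with unfiltered lists (0.138).

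CD8 T cells with and without Trnp1 UMIs were compared within each library, paired within log2 0.2 of UMIs. This gave 25, 18 and 14 pairs in ND replicates 1 to 3 and 298, 397 and 164 in MCDHFD replicates 1 to 3. In MCDHFD replicate 3 the 164 came from 368 cells with Trnp1. Median UMIs with and without Trnp1 still stood at 9542 and 9032 in MCDHFD replicate 2 and at 7473 and 6531.5 in MCDHFD replicate 3. Cells with Trnp1 carried less Ccl5 (-1.31), an effector and memory chemokine, less of the activating receptor Klrk1 (-1.12), the transcription factor Myb (-1.10), the calcium-binding S100a6 (-1.05), Anxa2 (-0.92), Ahnak (-0.53), Dennd4a (-0.43) and the exhaustion-linked Tox (-0.33), each lower in 6 of 6 libraries. Mctp2 (0.34) and the TGF-beta co-receptor Tgfbr3 (0.49) were higher in 6 of 6. The naming rule asks here for 1 direction in every library, so these counts of libraries add no support. Outside the naming rule, and chosen after the values were seen, Ikzf2 (-1.05), Ly6c2 (-0.39), Il2rb (-0.47) and Itgb1 (-0.58) were lower and Klhdc1 was higher (0.36). The MHC class II gene Cd74 (-1.26) and the B cell marker Cd79a (-1.07) were lower in the same cells. In all 26 of 6445 genes differed, 3 higher and 23 lower.

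Of 16 memory genes 6 were lower in cells with Trnp1 (median -0.35), and 3 of 8 central memory markers, with adjusted p = 0.0277 for each with an estimated correlation (camera, Benjamini-Hochberg). The 9 tested CD8 naive markers lay higher as a set at the same adjusted p, with 0 single members past the edgeR test. Of 8 MHC class II genes 4 were lower (adjusted p = 0.174 with an estimated correlation). Matching on cluster as well as depth left 6 genes, of which Ccl5 was at -0.26 and Cd74 at -0.82. DESeq2 called 5 genes, and the count was 7, 8 and 13 without MCDHFD replicate 1, 2 and 3.

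In B cells, 3 genes passed with diet alone: Ston1, an endocytic adaptor, rose by 4.62, and Wfdc21 and the transcription factor Sox4 fell by 4.06 and 2.59 (edgeR, Benjamini-Hochberg adjusted p = 0.0317, 0.00773 and 0.028). The model with list form gave rises of 2.28 in Fkbp5, 1.65 in the phosphatase Ptpn22, 1.42 in Tbc1d9, 1.405 in S100a6 and 1.31 in the cytokine receptor Il9r (0.29 between the filtered libraries). Agbl1 fell by 2.19 and the scaffold Akap12 by 1.72, both leading genes of a B cell cluster that held 503, 228 and 377 cells in ND replicates 1 to 3 and 79, 64 and 24 in MCDHFD replicates 1 to 3. In the other B cells Agbl1 was at -0.95 and Akap12 at -1.24. Ifi27l2a fell by 1.80, the cyclin Ccnd2 by 1.395 and Rgs2, a regulator of G protein signalling, by 1.25. Of 34 type I interferon genes 25 fell and none rose (median -0.77), with 29 lower when adjusted over the list alone and 15 lower without ND replicate 3. Rtp4 (-1.19), Ifi47 (-1.18) and Phf11b (-0.90) were among them, and 14 of 25 interferon gamma genes fell (H2-Q7 -1.15). Adjusted p with an estimated correlation was 0.262 and 0.286.

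Sterol metabolism genes fell in B cells. Of 27 cholesterol and fatty acid synthesis genes 13 fell and 1 rose, 17 and 1 when adjusted over the list alone, including the synthesis enzymes Idi1 (-1.29), Fdps (-1.18) and Cyp51 (-0.95). Adjusted p was 0.262 with an estimated correlation and 0.0298 with fry. The fatty acid import genes Cpt1a (1.03) and Slc25a20 (1.04) rose, and the fatty acid binding Fabp5 fell (-1.17). Cell cycle genes were lower in 9 of 30 cases (Mki67 -1.59), as was the germinal centre gene Rgs13 (-2.71). Macrophage genes rose with them, 7 of 11 red pulp macrophage markers, such as Hpgd (2.38), Vcam1 (1.90) and C1qb (1.90), and neutrophil Ltf fell (-3.60). In all 1076 of 12780 genes changed, 419 higher and 657 lower, against 3 with diet alone (627 at unadjusted p under 0.05, DESeq2 121), and 61 and 187 met the naming rule. Without 1 library the count ranged from 424 to 2799 with list form in the model, and with diet alone it was 0 without ND replicate 1, 2 or 3 or MCDHFD replicate 1 or 2, 1 without MCDHFD replicate 3, and 0 with the replicate number as a block.

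Cells of the monocyte and macrophage class had the deepest loss of interferon genes among the 8 classes by median. Of 34 type I interferon genes 23 fell and none rose (median -1.33), and 33 were lower when adjusted over the list alone. The number lower was 11, 3 and 12 without ND replicate 1, ND replicate 3 and MCDHFD replicate 1. With diet alone, Isg15 (-2.55), Ifi206 (-2.36) and Ifi205 (-3.32) passed, as did the complement receptor C5ar1 (2.98), with edgeR Benjamini-Hochberg adjusted p of 0.034, 0.0268, 0.0375 and 0.0169. All 4 calls were lost without ND replicate 1, ND replicate 3, MCDHFD replicate 1 or MCDHFD replicate 2, and all but C5ar1 without MCDHFD replicate 3. The list's adjusted p with an estimated correlation was 0.0694, and 0.024 with diet alone. Iigp1 fell by 3.63, Ifit3 and Ifit2 by 2.72 each and Irf7 by 1.58, where Ifit3 has a near-identical neighbour that could share its reads. From the interferon gamma list 14 of 26 fell, and of 11 MHC class II genes 7 fell, with H2-Ab1 at -1.75, H2-Eb1 at -1.66 and Cd74 at -1.56 (adjusted p = 0.0965 for each list with an estimated correlation). H2-Eb1 and Cd74 overlapped between the diets. H2-Ab1 and Ifi205 are also leading genes of the dendritic clusters, as is Adam23, which fell by 3.95 in this class.

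In the same class the iron-binding Lcn2 rose by 3.59, the matrix proteoglycan Vcan by 2.84, Chil3 by 2.75, Fkbp5 by 2.51 and the collagenase Mmp8 by 2.11, and 3 of 8 neutrophil granule genes rose (adjusted p = 0.0965 with an estimated correlation). The lipid droplet coat Plin2 (1.202), the fatty acid receptor Cd36 (1.38) and Apoe (0.89) rose, 3 of 17 lipid-associated macrophage genes, and Cd36 overlapped between the diets. The sterol genes Idi1 (-1.83) and Fdps (-1.64) were among 3 of 23 that fell, with 13 lower when adjusted over the list alone (adjusted p = 0.0965 with an estimated correlation). In all 126 of 9607 genes changed, 35 higher and 91 lower, against 4 with diet alone (432 at unadjusted p under 0.05, DESeq2 82), and 25 and 68 met the naming rule. Without ND replicate 3 the count was 15 with list form in the model, and with the replicate number as a block it was 0 with diet alone.

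NK cells showed higher Fkbp5 (1.69), Glis3 (1.75) and the Notch coactivator Maml3 (1.62). Socs2, an inhibitor of cytokine signalling, rose from 3 UMIs in the ND libraries to 78 in the MCDHFD libraries, a ratio of 23.5 in CPM (95% counting interval 7.74 to 116). Ifi27l2a fell by 2.23, the fractalkine receptor Cx3cr1 by 1.82, the maturation marker Klrg1 by 0.94, Ikzf2 by 1.46 and Xcl1 by 1.34, as did S100a8 and S100a9 (-1.89 and -1.64), abundant in neutrophils, and the histone gene Hist1h2ap (-1.51). Bcl2 rose by 1.18. Of 22 type I interferon genes 6 fell and none rose (median -0.33, adjusted p = 0.305 with an estimated correlation), with 1 lower and a median of -0.15 without ND replicate 3. B cell genes fell in 6 of 10 cases (Cd79a -1.06) while Cd8b1 rose (2.05). In all 407 of 8005 genes changed, 147 higher and 260 lower, and 52 and 148 met the naming rule. With diet alone edgeR called 0, 391 had an unadjusted p under 0.05 and DESeq2 called 2, and leaving out 1 library gave 80 to 900 genes with list form in the model. The smallest p with diet alone was that of Maml3 (1.65, edgeR, Benjamini-Hochberg adjusted p = 0.727), followed by Hbb-bs, S100a8, Mien1 and Cd300lf.

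Neutrophils carried more of the stefin genes, inhibitors of cysteine proteases, with Stfa2 up by 5.37, Cstdc5 by 4.96, Stfa1 by 4.14, Stfa3 by 4.12 and Csta2 by 3.95. These form a family of near-identical genes whose reads the counting could split, so the single values are uncertain. The immature granule genes Fcnb and Chil3 fell by 2.57 and 2.06, Olfml2b by 2.67, Acvrl1 by 2.36 and the histone gene Hist1h4k by 2.20. Of 15 granule and immaturity genes 3 fell (median -1.45) and 10 when adjusted over the list alone, and of 34 cell cycle genes 4 fell and 19 when adjusted over the list alone (Mcm5 -1.27, Pcna -1.15). Lipid-handling genes rose, 5 of 14, among them Apoe (1.95), Abca1 (1.85) and Plin2 (1.76). Adjusted p with an estimated correlation was 0.498 for each of these lists. Erythroid genes rose as well, 3 of 7, such as Alas2 (4.55) and Hbb-bt (5.26). In all 144 of 8696 genes changed, 90 higher and 54 lower, and 59 and 35 met the naming rule. With diet alone edgeR called 0 (999 at unadjusted p under 0.05, DESeq2 99), and the smallest p-values were those of Asprv1, Cstdc4, Stfa2l1, Alas2 and Acot1 (edgeR, Benjamini-Hochberg adjusted p = 0.13 each). A cluster of immature granule genes held 231, 78 and 44 cells in ND replicates 1 to 3 and 33, 19 and 65 in MCDHFD replicates 1 to 3, and without ND replicate 3 the count with list form was 13.

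Dendritic cells had lower cell cycle genes, 10 of 31 and 25 when adjusted over the list alone (median -1.37, adjusted p = 0.37 with an estimated correlation). The kinetochore genes Cenpf and Cenpe fell by 3.64 and 2.90, Ube2c by 2.81, Prc1 by 2.60 and Ccnb2 by 2.23. The growth factor receptor Fgfr1 rose by 2.79, Ocstamp by 2.50 and St6galnac3 by 2.37. Prkcq (2.74) and Skap1 (2.54), of T cell receptor signalling, rose together with the T cell markers Cd3e (2.44), Cd8b1 (2.41) and Trbc2 (2.36). Of 13 naive T cell genes 5 rose (Lef1 2.61, adjusted p = 0.164 with an estimated correlation). Of 28 type I interferon genes 3 fell and none rose (Isg15 -1.25, median -0.37), with 1 lower without ND replicate 2 or MCDHFD replicate 3 and a median of -0.0749 without MCDHFD replicate 2. In all 137 of 7997 genes changed, 75 higher and 62 lower, and 48 and 36 met the naming rule. With diet alone edgeR called 0 (410 at unadjusted p under 0.05, DESeq2 28), with Wfdc17, Fgfr1, Ston1, Ocstamp and Lgmn at the smallest p (edgeR, Benjamini-Hochberg adjusted p from 0.165 to 0.201). The class held 74, 88 and 76 cells in ND replicates 1 to 3 at median depths of 11826, 8217 and 10988 UMIs, and in MCDHFD replicates 1 to 3 the median depths were 6541, 6103 and 5311. With list form the count was 60 without ND replicate 2.

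Erythroid cells gained Acot1, a fatty acyl-CoA thioesterase, from 1 UMI in the ND libraries to 275 in the MCDHFD libraries, past the test with diet alone (edgeR, Benjamini-Hochberg adjusted p = 0.00294). The ratio was 363 in CPM with a 95% counting interval from 64.5 to 14373, and near-identical Acot genes could share its reads. Disc1 rose by 3.95, the phosphodiesterase Pde3b by 1.88, Gsta4 of lipid peroxide detoxification by 1.85, Cpd by 1.76, the fatty acid oxidation enzyme Hadh by 1.33 and the serine synthesis enzyme Psat1 by 1.36. Ifi27l2a fell by 2.18, the immunoproteasome subunit Psmb9 by 1.35, Ifi27 by 1.26 and Rtp4 by 3.18. Of 17 type I interferon genes 2 fell and 11 when adjusted over the list alone (median -1.13, adjusted p = 0.0929 with an estimated correlation). In all 14 of 8580 genes changed, 10 higher and 4 lower, against 1 with diet alone (297 at unadjusted p under 0.05, DESeq2 12), and 7 and 3 met the naming rule. The Acot1 call with diet alone was lost without ND replicate 1 or 3 or MCDHFD replicate 1.

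**Figure D4:**
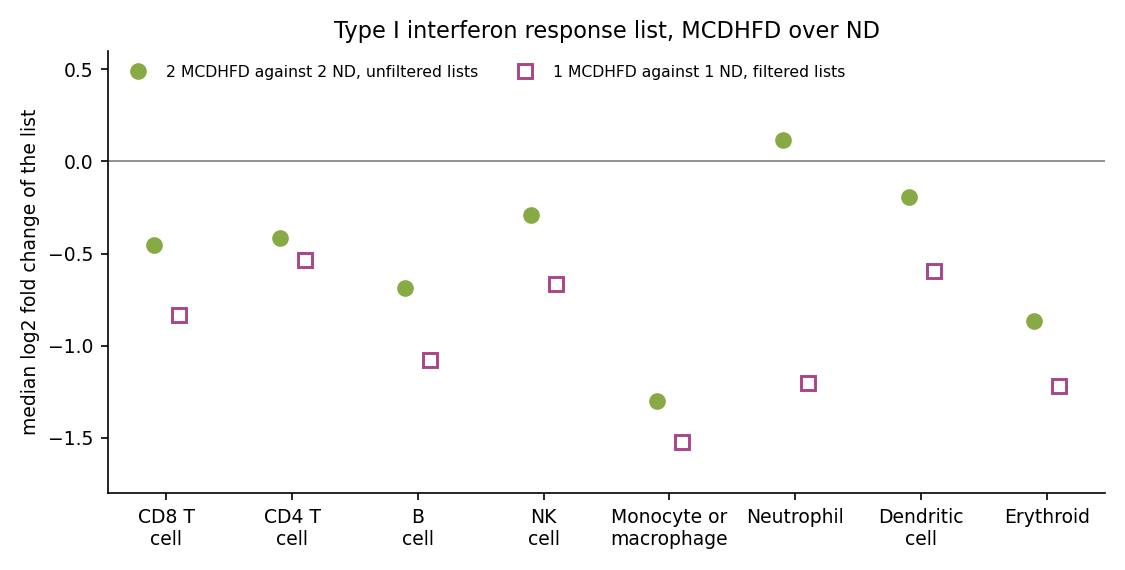
Median log2 fold change, MCDHFD over ND, of the type I interferon response list in 8 cell classes, with green points for the unfiltered and open squares for the filtered libraries. Monocytes and macrophages lay lowest at -1.30 and -1.52, and neutrophils at 0.12 and -1.20.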

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

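The tests of the 3 patterns weighed here were chosen after the results were seen, except that each library was left out in turn by plan. Higher Trnp1 in CD8 T cells with MCDHFD could come from the library type, from free RNA or from the mix of CD8 clusters. The smaller log2 difference among the unfiltered and between the filtered libraries was 3.59, which excludes library type as the sole source. Free RNA would reach B cells alike, yet CD8 T cells held at least 89.3 times the Trnp1 CPM of B cells in each MCDHFD library, with B cells at their upper counting limit. Within the 2 larger CD8 clusters the smaller difference was 3.78, so the mix of clusters does not give it either. A rise of Trnp1 within CD8 T cells is the remaining hypothesis, with 3 libraries per diet.

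Lower type I interferon genes with MCDHFD could come from the library type, from fewer cells of interferon-high clusters or from 1 library. Over CD8 T cells, CD4 T cells, B cells and monocytes or macrophages and both list forms, the median nearest 0 was -0.41. The test of library type covers only these 4 classes, chosen after the values were seen. Among the unfiltered libraries, medians of the other classes were 0.12 in neutrophils, -0.195 in dendritic cells, -0.29 in NK cells and -0.87 in erythroid cells. Within 4 T cell clusters it was -0.35 with at least 4 members called lower in each, so a changed share of interferon-high clusters is not needed there. It was -0.36 within 8 B cell clusters and -0.43 within 4 monocyte or macrophage clusters, but 2 and 1 of these had fewer than 4 called. The rule of at least 4 called in each cluster was thus not met in these classes. Each B cell cluster still had 3 to 15 members lower and 0 higher, which argues against the share as the sole source there. So do monocyte or macrophage clusters 9, 18 and 19, with 28, 6 and 4 lower and 0 higher. Cluster 23 had 0 called, so the share stays open there. Whether fewer interferon-high cells inside each cluster play a part was not tested in any class. Leaving out each library in turn, the median nearest 0 over the 4 classes was -0.34, so no 1 library gives the direction in these classes. Outside them, the neutrophil median was above 0 without ND replicate 2 (0.036) or MCDHFD replicate 3 (0.0384). The dendritic cell median was -0.0749 without MCDHFD replicate 2. Without ND replicate 3, however, only 3 members were called lower in CD8 T cells and 3 in monocytes or macrophages. How many members change thus stays open, and a weaker interferon response may be the biological reading of the direction in these 4 classes, as a hypothesis.

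Higher Fkbp5 in every class tested could come from the library type, from handling stress or from glucocorticoid exposure. The smallest log2 difference over 8 classes and both list forms was 1.12. Handling stress would raise heat shock and dissociation genes, and their median lay above 0 in 1 of 8 classes. Glucocorticoid exposure is possible but undecided. Its target list without Fkbp5 had a median above 0 in 8 of 8 classes. Camera called that list higher in all 8 at the preset correlation, with unadjusted p from 0.0346 to 0.203 at an estimated one. Part of it had been looked at first. Without Tsc22d3, Zbtb16, Per1, Ddit4, Il7r and the heat shock and dissociation genes, 4 to 8 members per class remained. Their median lay above 0 in 8 of 8 classes. Camera at the preset correlation called 4 classes, yet with an estimated correlation it called 0 (lowest adjusted p = 0.384). With so few members this last test cannot decide. In erythroid cells Fkbp5 itself did not pass.

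The diet effect differed between CD8 and CD4 T cells for 73 genes. The differences were -2.30 for Hdac9, 7.76 for Igkv9-120, an immunoglobulin segment with too few counts to be tested within either class, 0.82 for Lgals1, -0.50 for Bcl2 and -0.93 for Atp1b1. An unnamed cluster with B cell and pancreatic acinar genes, cluster 31, held 13 cells in MCDHFD replicate 2 and 79 in MCDHFD replicate 3. In barcodes of at most 100 UMIs, Trnp1 reached 6.38 CPM in MCDHFD replicate 1 and 13.2 in MCDHFD replicate 2, against 0 in ND replicate 1 and 1.52 in ND replicate 3.

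The 6 libraries were also regrouped in all 10 splits of 3 against 3, too few for a share under 0.05. With list form in the model, the real split alone gave the most genes in each class, and the highest other split gave 1 in CD8 T cells, 0 in CD4 T cells, 0 in B cells, 1 in NK cells, 4 in monocytes or macrophages, 0 in neutrophils, 0 in dendritic cells and 1 in erythroid cells. With diet alone the real split gave 1, 0, 3, 0, 4, 0, 0 and 1 genes, and the highest other 0, 0, 0, 1, 0, 473, 2 and 6. The 473 genes in neutrophils came from ND replicates 1 and 2 with MCDHFD replicate 3 against the rest, which puts both filtered libraries on 1 side. Every other split with both on 1 side gave 0 genes in neutrophils, so list form alone does not give the 473. The cluster of immature granule genes held 231, 78 and 65 of the 503, 197 and 173 neutrophils of these libraries. In ND replicate 3 and MCDHFD replicates 1 and 2 it held 44, 33 and 19 of 162, 337 and 389. Whether this mix gives the 473 was not tested. The 6 genes in erythroid cells came from ND replicates 1 and 3 with MCDHFD replicate 1 against the rest, again with both filtered libraries together, so 2 of 10 splits were as large there. For the difference between CD8 and CD4 T cells the highest other split gave 3 genes, and for lists in CD8 T cells 13 against the real 17 with diet alone and 15 against 19 with list form. For cells with against without Trnp1 UMIs, 1 of 32 swaps reached the real count, and the highest other gave 21.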

How the results depend on the processing

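The limits are 3 libraries per diet, 2 library types, and counts of genes that depend on whether list form is in the model. Across all settings except those repeated on the model with list form, 114 named genes gave 1957 values, all in the direction reported and 0 reversed. Of these, 54 under planned settings were weaker, that is, called with diet alone and not there. Only genes called with diet alone could become weaker. These were 1 in CD8 T cells, 3 in B cells, 4 in monocytes or macrophages and 1 in erythroid cells. The 54 should therefore not be set against all 1957 values, most of which belong to genes that diet alone did not call. The naming rule asks for a large change without overlap between the diets, so reversals were unlikely from the start. Among the other results, planned settings left 236 values the same, 72 moved, 15 weaker, 3 stronger and 21 reversed, and settings added after the data were seen left 119 the same, 90 moved, 13 stronger and 8 reversed. Stronger means that a result passed there and not in the planned model without list form, and does not speak of a larger log2 value. The causes of these changes were not tested. Counts are of genes past edgeR or DESeq2 with Benjamini-Hochberg adjusted p under 0.05.

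List form in the model gave 394 genes in CD8 T cells, 458 in CD4 T cells, 1076 in B cells, 407 in NK cells, 126 in monocytes or macrophages, 144 in neutrophils, 137 in dendritic cells and 14 in erythroid cells, all moved from 1, 0, 3, 0, 4, 0, 0 and 1. Trnp1 in CD8 T cells was 3.96 (edgeR, Benjamini-Hochberg adjusted p = 4.75e-10, stronger). The shares of CD4 T cells (0.45, adjusted p = 0.013) and B cells (-0.47, 0.0017) were stronger, and erythroid cells reversed (-0.17). NK cells had 18 lists. For shares and lists, list form was added after the data were seen.

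DESeq2 with diet alone gave 22, 39, 121, 2, 82, 99, 28 and 12 genes in the same order, and with list form 184 in CD8 T cells, 275 in CD4 T cells, 69 in NK cells, 210 in monocytes or macrophages, 519 in neutrophils and 70 in dendritic cells. DESeq2 gave Trnp1 4.14 (Benjamini-Hochberg adjusted p = 2.81e-10, stronger), an interaction count of 19 and 5 genes for cells with against without Trnp1. It gave no adjusted p for the interaction of Trnp1.

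Without a filter on low counts, diet alone gave 3 genes in CD8 T cells, 43 in NK cells, 18 in monocytes or macrophages, 41 in neutrophils, 119 in dendritic cells and 44 in erythroid cells. With list form it gave 660 in CD8 T cells, 1745 in B cells, 657 in monocytes or macrophages, 1078 in neutrophils, 539 in dendritic cells and 119 in erythroid cells. Trnp1 was 4.14 (edgeR, Benjamini-Hochberg adjusted p = 0.0223, stronger), its interaction -2.92 (7.34e-05, stronger), the interaction count 136 and the count with against without Trnp1 55.

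The 4 libraries with unfiltered lists, a setting added after the data were seen, gave 958 genes in CD8 T cells, 726 in CD4 T cells, 2825 in B cells, 881 in NK cells, 86 in monocytes or macrophages, 917 in neutrophils, 60 in dendritic cells and 1 in erythroid cells. Trnp1 was 3.67 (edgeR, Benjamini-Hochberg adjusted p = 1.16e-08, stronger). Shares were stronger for CD4 T cells (0.40, adjusted p = 0.0399), B cells (-0.37, 3.42e-06) and dendritic cells (1.01, 0.0212), and reversed for NK cells (0.27), neutrophils (0.0316), erythroid cells (-0.80) and interferon-stimulated CD8 T cells (0.11). The interaction count was 35, and lists numbered 20 in NK cells, 16 in dendritic cells and 12 in erythroid cells.

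A batch term of 3 levels, also added after the data were seen, gave 306, 165, 505, 86, 46, 40, 98 and 7 genes in the order of the classes above. ND replicate 1 is the only library of its level, so the term takes it up. The diet effects of this setting thus rest on the other libraries. Trnp1 was 4.28 (edgeR, Benjamini-Hochberg adjusted p = 1.12e-13, stronger) and the B cell share -0.53 (0.001, stronger). Shares of neutrophils (0.31), erythroid cells (-0.0506) and plasma cells (0.44) reversed.

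With the replicate number as a block, CD8 T cells, B cells and monocytes or macrophages each had 0 genes and erythroid cells 2, and NK cells had 16 lists. The shares of CD8 T cells (0.63, edgeR, Benjamini-Hochberg adjusted p = 0.338) and monocytes or macrophages (1.05, 0.138) did not pass with the block, and those of neutrophils (0.00456), erythroid cells (-0.16) and plasma cells (0.0266) reversed. The numbers do not pair the libraries: in CD8 T cells, libraries of 1 number correlated at 0.55, -0.71 and -0.67, so the block result does not speak of a smaller effect.

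At least 2000 UMIs per cell gave 0 genes in B cells, and reversed shares of erythroid cells (-0.00711) and plasma cells (0.0407). With predicted doublets kept, neutrophils had 357 genes with list form, and the NK share was 0.0407 (reversed). With at least 500 UMIs and 300 genes, the shares of CD8 T cells (0.59, edgeR, Benjamini-Hochberg adjusted p = 0.0517) and monocytes or macrophages (1.15, 0.0517) were weaker. Naive CD8 T cells reversed at 0.5 times the resolution (0.0521) and at 1.5 times (0.0352). List form by class gave the Trnp1 interaction as -2.92 (edgeR, Benjamini-Hochberg adjusted p = 0.00087, stronger). Cells with against without Trnp1 gave 6 genes matched on UMIs and cluster and 110 not matched.

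With diet alone and an estimated correlation, camera called 0 lists in CD8 T cells, 0 in CD4 T cells, 0 in B cells, 0 in NK cells, 4 in monocytes or macrophages, 0 in neutrophils, 0 in dendritic cells and 1 in erythroid cells. The comparison by Trnp1 had 5. With fry these were 0, 5, 1, 0, 3, 0, 0, 1 and 5, against 17, 15, 16, 6, 11, 16, 10, 6 and 10 at the preset correlation. With list form in the model, camera at an estimated correlation called 0 lists in every class. In the same order of classes, fry then called 0, 0, 2, 2, 4, 0, 3 and 2, and camera at the preset correlation 19, 19, 13, 18, 12, 17, 12 and 7.

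Leaving out ND replicates 1, 2 and 3 and MCDHFD replicates 1, 2 and 3 in turn, with diet alone, gave 0, 0, 0, 1, 0 and 1 genes in CD8 T cells, 0, 0, 0, 0, 0 and 1 in CD4 T cells and in B cells, 0, 5, 0, 0, 0 and 1 in monocytes or macrophages, 0, 0, 0, 0, 0 and 64 in neutrophils, 0, 1, 0, 0, 1 and 2 in erythroid cells, and 0 each time in NK and dendritic cells. With list form the order gave 273, 1010, 180, 248, 173 and 1026 in CD8 T cells, 184, 731, 309, 230, 278 and 720 in CD4 T cells, and 505, 2782, 424, 697, 459 and 2799 in B cells. It gave 80, 859, 123, 131, 107 and 900 in NK cells, 53, 77, 15, 55, 119 and 82 in monocytes or macrophages, and 40, 1023, 13, 55, 215 and 1017 in neutrophils. Dendritic cells had 80, 60, 115, 99, 94 and 69, and erythroid cells 8, 4, 17, 4, 23 and 3. The counts with list form without ND replicate 2 or MCDHFD replicate 3 rest on the 4 libraries with unfiltered lists, since list form takes up the 1 filtered library left. They are close to repeats of that setting and not separate evidence. Cells with against without Trnp1 gave 33, 34, 38, 7, 8 and 13.

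Without 1 library, Trnp1 in CD8 T cells ranged from 3.43 (without MCDHFD replicate 3) to 4.49 (without MCDHFD replicate 1), its thinned share difference from 5.70 to 12.8 points, its interaction from -3.22 to -2.39 and the interaction count from 58 to 93. The Trnp1 interaction passed without MCDHFD replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0286), 2 (0.0274) and 3 (0.0284). It did not pass without ND replicate 1 (0.422), 2 (0.344) or 3 (0.221). Syt6 with diet alone lost its call without ND replicate 1 (0.0907), 2 (0.0883) or 3 (0.177) or MCDHFD replicate 2 (0.0614), and Acot1 in erythroid cells without ND replicate 1 (0.0705) or 3 (0.0624) or MCDHFD replicate 1 (0.0539).

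Shares without 1 library ranged from 0.59 to 0.67 for CD8 T cells, 0.25 to 0.61 for CD4 T cells, -0.56 to -0.29 for B cells, 0.88 to 1.28 for monocytes or macrophages, 0.39 to 1.03 for dendritic cells, -0.91 to -0.31 for plasmacytoid dendritic cells and -1.05 to -0.40 for basophils or mast cells. The CD8 call was lost in each case (edgeR, Benjamini-Hochberg adjusted p = 0.226, 0.0718, 0.178, 0.229, 0.123 and 0.0726), and that of monocytes or macrophages held only without ND replicate 2 (0.0336). Some ranges crossed 0: NK cells -0.27 to 0.26 (reversed without MCDHFD replicate 3), neutrophils -0.35 to 0.23 (ND replicate 1), erythroid cells -0.80 (MCDHFD replicate 3) to 0.47, plasma cells -0.28 to 0.37 (ND replicate 1, and 0.09 and 0.15 without MCDHFD replicates 1 and 2) and unnamed cells -0.30 (MCDHFD replicate 3) to 0.86. Naive CD8 T cells ranged from -0.24 to 0.16 (reversed at 0.07, 0.09 and 0.16 without ND replicate 1, ND replicate 3 and MCDHFD replicate 3) and interferon-stimulated ones from -0.45 to 0.16 (reversed without ND replicates 2 and 3 and MCDHFD replicate 2, at 0.03, 0.16 and 0.06). Central memory cells ranged from -0.28 to -0.10, effector cells from -0.75 to -0.01 and CD8 T cells without a named state from 0.01 to 0.16.

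For the type I interferon list with list form, leaving out ND replicate 3 lowered the members called from 16 to 3 in CD8 T cells, 11 to 7 in CD4 T cells, 25 to 15 in B cells, 6 to 1 in NK cells and 23 to 3 in monocytes or macrophages. NK cells had 2, 3 and 2 without ND replicate 1, MCDHFD replicate 1 and MCDHFD replicate 2, and monocytes or macrophages 11 and 12 without ND replicate 1 and MCDHFD replicate 1. Dendritic cells went from 3 to 1 without ND replicate 2 or MCDHFD replicate 3, with medians of -0.218 and -0.149, and had a median of -0.0749 without MCDHFD replicate 2. Erythroid cells went from 2 to 0 without ND replicate 2, MCDHFD replicate 1 or MCDHFD replicate 3 and to 1 without ND replicate 1. The NK median was -0.15 without ND replicate 3. In neutrophils, with 0 members called on all libraries, the median was 0.036 without ND replicate 2 and 0.0384 without MCDHFD replicate 3, with 1 called lower in each, and 2 were called without MCDHFD replicate 2.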

Other observations

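Cpt1a and Acot1, 2 genes of fatty acid handling brought together here after the values were seen, rose in several classes (edgeR, model with list form). Cpt1a, of mitochondrial fatty acid import, rose by 1.06 in CD8 T cells, 1.07 in CD4 T cells, 1.03 in B cells and 1.198 in dendritic cells. The thioesterase Acot1, whose reads near-identical Acot genes could share, rose by 1.53 in B cells, 2.41 in monocytes or macrophages and 2.42 in neutrophils. The list for fatty acid oxidation and uptake passed with an estimated correlation in none of the classes and with fry in B cells (adjusted p = 0.0298), with 1 of 17 members higher in CD8 T cells, 2 of 18 in B cells and 1 of 17 in dendritic cells (adjusted p = 0.464, 0.477 and 0.222 with an estimated correlation).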
